A study of Homo sapiens with 8 samples.

How the data were processed

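The data are 8 Agilent 2-colour whole human genome arrays of total RNA from 2 established human cell lines, Caco2 and HPAC. Per the labels, cells of each line were grown at 20% O2 to 70% confluence, then 2 flasks were moved to 2% O2 and 2 flasks stayed at 20% O2 for 72 h, all at 37 °C and 5% CO2. The medium, the same for both lines, was Williams E with 10% fetal calf serum, glutamine, insulin, dexamethasone and antibiotics. Per the labels, 1 µg of RNA was reverse transcribed from an oligo-dT primer, amplified once by in vitro transcription and labelled with Cy3 or Cy5. Each hypoxic RNA was hybridized with a normoxic RNA of the same line on 2 arrays with the dyes swapped, which gives 4 arrays and 2 RNA pairs per line. The 4 Caco2 arrays shared a slide and a scan and the 4 HPAC arrays shared another, so slide and line cannot be told apart, whereas hypoxia and normoxia were compared within every array.

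The deposited scanner files came from Agilent Feature Extraction 9.5.1.1, with probe positions on build hg18. They hold the mean spot brightness and the median local background of each channel as an intensity on a linear scale, with no normalization by the authors. Their processed signals are intensity values that Feature Extraction background-subtracted and dye-normalized, per the file headers. The deposited log ratio is a log10 ratio of red over green processed signal, per the file headers, and is exactly 0 for 17.3 to 24.3% of spots. The authors also deposited a value table in log2 units, and the further normalization behind it is not stated. Checked against the scanner files, it holds log2 of hypoxia over normoxia, with slopes of 0.999 to 1.01 and correlations of 0.895 to 0.9997 against the log ratios of the same arrays, and medians of -0.13 to 0.14 per array.

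Ratios were computed from the mean spot intensities with limma 3.58.1 in R 4.3.3, by normexp background correction with an offset of 50 and loess normalization within each array. Signs were turned so that hypoxia is the numerator, spots of one probe were averaged, and the 2 dye-swapped arrays of an RNA pair were averaged to 1 replicate. Control spots were left out, and spots that Feature Extraction marked as outliers were set to missing on the array concerned, which is 0.189 to 1.27% of the 43376 spots per array. A pair with a missing array was taken as missing, so 83 of the Caco2 and 510 of the HPAC genes lack at least 1 RNA pair. In Caco2 pair 1 is missing for 27 genes and pair 2 for 57, and in HPAC for 424 and 153. Genes that lack 1 pair rest on the other. Some lack both, mostly in HPAC, and these have no test but are included in the numbers of measured genes. A probe counted as measured in a line when Feature Extraction called it well above background on all 4 arrays of the line in the hypoxia channel, or on all 4 in the normoxia channel. A gene with several probes was represented by its brightest probe over all arrays and channels. Symbols came from the RefSeq gene table of GRCh38.p14: of 41000 probes, 23680 were named by accession, 2802 by symbol and 1125 by synonym, and 13393 without a current symbol were kept as unnamed rows. Counts of genes below include these unnamed rows.

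No count depth exists for arrays. Between 55.5% and 65.5% of probes per channel were above background, no spot was saturated, and the number of arrays limits the precision. The design could not separate effects of the flask, since the 2 RNA pairs of a line are the only replicates. The p-values of single genes rest on the spread between these pairs, pooled over both lines and drawn toward a prior shared by all genes. The list p-values from camera with a preset correlation and the permutation p, both described below, compare genes with other genes. They do not measure the spread between RNA pairs.

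One limma model (lmFit and eBayes) with a coefficient per line was fitted over the 4 RNA pairs, with 2 residual and 4.87 prior degrees of freedom and a prior SD of 0.130 on the log2 scale. It tested the change in Caco2, the change in HPAC, the difference (HPAC change minus Caco2 change) and the average of both changes, all two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The lines were tested over the genes measured in them, the other contrasts over the genes measured in both. The similarity of the lines was given as a correlation across genes, without a p, since genes are not independent replicates. Lists of 26 pathways, cell states and marker sets with 536 entries were fixed before the data were examined, as were the comparisons and the rule for named genes. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 26 lists in Caco2 and 25 in HPAC, and separately over the lists for the difference, with at least 3 measured members per list. Genes with a missing RNA pair in either line were left out of these tests, so a test can rest on fewer genes than the counts given beside it. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were run beside it. With an estimated correlation the spread rests on 2 residual degrees of freedom, and no list in any contrast passed. Some estimates in Caco2 lay well above the preset: 0.43 for metallothioneins, 0.36 for NF-kB, 0.24 for stress and 0.23 for glycolysis genes. Others lay near the preset, such as HIF targets (-0.0037) and the respiratory chain (-0.0093). Where the correlation between genes is above the preset, the camera p with the preset is too small.

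The text names, for each line, the 8 largest increases and 8 largest decreases past the threshold with a gene symbol and the same direction on all 4 arrays. It also draws on up to 4 members per list with the smallest p in the line, and always on CA9, VEGFA, NDRG1, LDHA, PDK1, BNIP3, EGLN3, ADM, HIF1A and EPAS1. For the difference it names the 6 largest each way for which both RNA pairs of one line lie above both of the other, and for the average the 5 largest each way with the same direction on all 8 arrays.

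Alternatives changed one choice at a time: no background correction, Agilent's log ratios, the deposited value table, median centring, scaling between arrays, no filter and a strict filter on dim probes, the mean of a gene's probes, an intensity trend in the prior, each line fitted alone, 8 arrays with a dye term and the RNA pair as a block, RNA extracts without their array pairing, a 2-fold bound, and each RNA pair left out in turn. Choices added after seeing the data were Caco2 replicate 1 taken from array 1 alone, only rows with a symbol, and every alternative for the lists tested for the difference. The fit was tested on simulated data with 200 changed genes per line, independent noise for each gene and the same spread in both lines. Far more genes passed in the data themselves (46.5% in Caco2 and 40.2% in HPAC), so the recovery rates given next need not hold there. It recovered 60 of 65 changes of 1 log2 unit in Caco2 and 60 of 66 in HPAC, 7 of 67 and 4 of 67 changes of 0.5, and called 9 of 18179 and 15 of 17699 unchanged genes. For the difference it recovered 212 of 361 genes with 10 false calls. Within the lines, camera with the preset correlation called 4 of 4 shifted lists and 0 of 37 unshifted lists that share no gene with a shifted one. Unshifted lists that share genes with a shifted one were not counted. The list test of the difference was not simulated. As the simulated genes were independent, these list counts cannot show how often lists of correlated genes are called falsely. Figures were drawn with matplotlib 3.10.9. No deposited array was left out.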

Results

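RNA of Caco2, a line from a human colorectal adenocarcinoma, and HPAC, a line from a human pancreatic adenocarcinoma, was measured on arrays. Cells kept for 72 h at 2% O2 (hypoxia) were compared with cells kept at 20% O2 (normoxia). Each line has 2 pairs of hypoxic and normoxic RNA and 4 arrays, with each pair hybridized on 2 arrays with the dyes swapped. On these arrays 55.5% to 65.5% of 41000 probes per channel were above background. In Caco2 18416 genes were measured, 12817 of them with a current symbol, and in HPAC 17935, of which 12355 have a symbol. Both lines share 16474 measured genes. Changes are log2 ratios of hypoxia over normoxia, given as the mean of n = 2 RNA pairs ± SE. The SE, here and in the figures, is that of the fitted model, which pools the spread over both lines and draws it toward a prior. It is therefore equal in both lines where no pair is missing, and is not the spread of a line's own pairs. A positive value means a higher signal at 2% O2. The median SE was 0.0893 per line. Positions are those of the probe on hg18.

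The comparison within Caco2 asks which transcripts change in this line after 3 days of low oxygen. By camera with a preset correlation, the lists of hypoxia-inducible factor (HIF) targets, glycolysis genes, metallothioneins, NF-kB genes and stress genes were higher at 2% O2. The lists of mitosis (24 of 31 genes lower), Wnt (12 of 19) and respiratory chain genes (18 of 41) were lower. None of these list calls held with an estimated correlation (adjusted p from 0.369 to 0.388). That version rests on 2 residual degrees of freedom and passed no list at all, so it cannot tell these lists from others. By fry, which does not compare them with other genes, each passed in the same direction (adjusted p from 0.0029 to 0.0215). ADM, which encodes the vessel-dilating peptide adrenomedullin, was 10.2-fold higher (log2 3.36 ± 0.10, adjusted p = 7.61e-06; chromosome 11, 10285356 to 10285415). CA9, a cell-surface carbonic anhydrase, was 7.85-fold higher (2.97 ± 0.092; chromosome 9, 35667817 to 35669204). BNIP3, a receptor for the removal of mitochondria, was 7.36-fold higher (2.88 ± 0.092; chromosome 10, 133631301 to 133631360). Of the other genes fixed in advance, PDK1 rose by 2.36 ± 0.088, the HIF hydroxylase EGLN3 by 2.35 ± 0.084 and NDRG1 by 2.02 ± 0.078. VEGFA rose by 1.56 ± 0.079, LDHA by 1.48 ± 0.085 and EPAS1, which encodes HIF-2 alpha, by 0.60 ± 0.094. Other VEGFA probes gave 1.95 to 2.33 in Caco2. HIF1A, which encodes HIF-1 alpha, changed by -0.68 ± 0.12 (adjusted p = 0.00409; chromosome 14, 61284598 to 61284657). Each of these 10 genes had the same direction on all 4 arrays. Without Caco2 replicate 2, EPAS1 in Caco2 (0.50, adjusted p = 0.0894) and HIF1A in Caco2 (-0.59, adjusted p = 0.099) no longer passed.

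**Figure D1:**
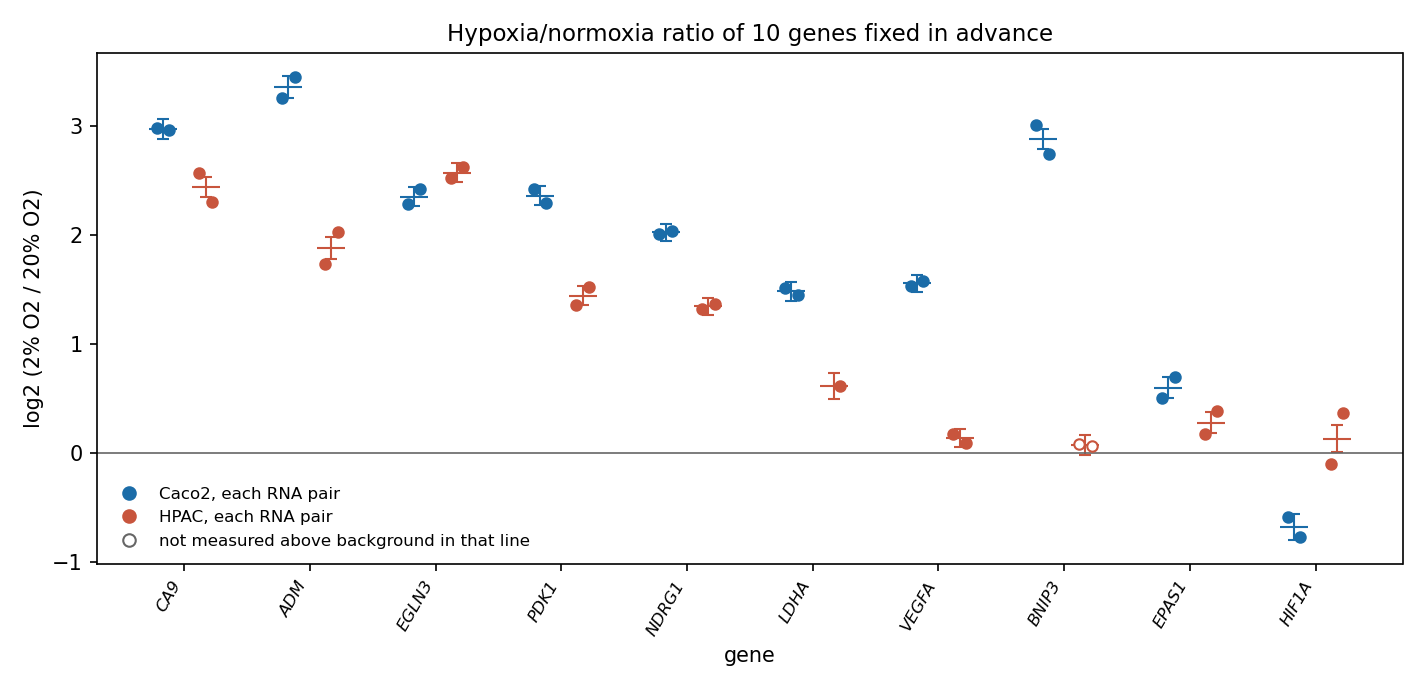
Log2 ratio of 2% over 20% O2 (y axis) for the 10 genes fixed in advance (x axis), with blue for Caco2 and red for HPAC; dots are single RNA pairs, horizontal bars the mean and error bars the SE, and open dots mark a gene not measured above background. ADM and CA9 lie highest in Caco2 at 3.36 and 2.97, EGLN3 and CA9 highest in HPAC at 2.57 and 2.44, and VEGFA lies at 1.56 in Caco2 and 0.14 in HPAC.

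Among the HIF target genes, 26 of 29 measured members rose in Caco2 and 0 fell (camera adjusted p = 2.4e-14, adjusted p = 0.369 with an estimated correlation). The counts were 26 up and 1 down adjusted over the list alone. DDIT4, an inhibitor of mTOR signalling, changed by 3.02 and ANKRD37 by 2.76. Of the glycolysis and glucose uptake genes 25 of 26 rose (camera adjusted p = 1.3e-12, adjusted p = 0.388 with an estimated correlation). The counts were 25 up and 1 down adjusted over the list alone. The largest increases were those of PFKFB4 (2.76), which sets the level of a glycolytic activator, and the enolase gene ENO2 (2.73). Collagen-modifying and matrix crosslinking genes changed in both directions, with 8 of 15 higher and 3 lower (camera adjusted p = 0.00563, adjusted p = 0.462 with an estimated correlation). The counts were 9 up and 3 down adjusted over the list alone. LOX, a crosslinker of collagen and elastin, rose by 3.20 ± 0.094, and the prolyl hydroxylase gene P4HA1 by 1.68. All 11 metallothionein genes, whose products bind zinc and copper, were measured and 10 rose (camera adjusted p = 2.12e-07, adjusted p = 0.388 with an estimated correlation), led by MT2A at 3.05. MT1M was at least 2.29-fold higher, since no normoxic channel was above background. Probes of these closely related genes can bind each other's transcripts.

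Of the unfolded protein and amino acid stress list, 17 of 25 members rose and 1 fell (camera adjusted p = 1e-06, adjusted p = 0.388 with an estimated correlation). ATF3 changed by 2.93 (another probe gave 2.31), DDIT3, which encodes the stress factor CHOP, by 2.09, and TRIB3 by 1.72, while the serine synthesis gene PSAT1 fell by 0.65. NF-kB and inflammatory signalling genes rose in 15 of 18 cases (camera adjusted p = 6.32e-07, adjusted p = 0.388 with an estimated correlation). The counts were 15 up and 1 down adjusted over the list alone. TNFAIP3, an inhibitor of NF-kB signalling, changed by 2.53 and PTGS2, the inducible cyclooxygenase, by 2.48. In the list of epithelial junctions and mesenchymal transition 12 of 15 genes rose (camera adjusted p = 2.23e-05, adjusted p = 0.388 with an estimated correlation). The members that rose include the tight junction genes CLDN3 (0.81) and OCLN (0.73). They also include the integrin gene ITGA5 (1.89) and the repressor of epithelial genes SNAI1 (1.18). Of the enterocyte genes 11 of 22 rose and 4 fell (camera adjusted p = 0.0159, adjusted p = 0.389 with an estimated correlation), with the apolipoprotein genes APOC3 at 2.02 and APOA4 at 1.75 (1.11 with another probe). With the strict filter on dim probes the camera adjusted p was 0.103. Of the histone and DNA demethylases 8 of 14 rose (camera adjusted p = 0.00255, adjusted p = 0.388 with an estimated correlation), among them the HIF target KDM3A (2.18). The counts were 9 up and 0 down adjusted over the list alone.

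Cell cycle and mitosis genes fell in 24 of 31 cases in Caco2, and 1 rose (camera adjusted p = 8.4e-06, adjusted p = 0.388 with an estimated correlation). The mitotic kinesin gene KIF20A changed by -1.15 ± 0.11, the cyclin gene CCNB1 by -1.13 ± 0.085 and the mitotic kinase gene PLK1 by -0.97 ± 0.084. CCNB1 and PLK1 were not in the camera test, since each lacks an RNA pair in HPAC. Of the DNA replication and repair genes 12 of 30 fell (camera adjusted p = 0.0159, adjusted p = 0.388 with an estimated correlation). PCNA, the sliding clamp of DNA polymerases, changed by -1.34 and UNG, a uracil-removing repair enzyme, by -1.05. Wnt targets and intestinal stem cell genes fell in 12 of 19 cases and 1 rose (camera adjusted p = 9.51e-05, adjusted p = 0.388 with an estimated correlation). AXIN2, a feedback inhibitor of Wnt signalling, changed by -1.10, and other AXIN2 probes by -0.89 and -0.096. The stem cell marker LGR5 changed by -0.96. Respiratory chain genes fell in 18 of 41 cases and none rose (camera adjusted p = 0.000899, adjusted p = 0.388 with an estimated correlation), with a median of -0.24. ATP5MC3 changed by -0.59 and SDHC by -0.49. ATP5MC3 in Caco2 missed the threshold without Caco2 replicate 1 (adjusted p = 0.0596). So did SDHC in Caco2 without Caco2 replicate 1 or 2 (adjusted p = 0.072 and 0.0844).

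Some smaller Caco2 lists passed at weaker levels. Of 16 iron and heme genes 7 rose and 1 fell (camera adjusted p = 0.0395, adjusted p = 0.388 with an estimated correlation). The counts were 8 up and 1 down adjusted over the list alone. They include the iron importer SLC11A2 at 1.20, of which other probes gave 0.88 and -0.13. This call was lost without Caco2 replicate 1 (adjusted p = 0.0756) and with only rows that have a symbol (adjusted p = 0.0902). Of 9 glucocorticoid-responsive genes 6 rose and 2 fell (camera adjusted p = 0.0245, adjusted p = 0.388 with an estimated correlation). GADD45B changed by 2.10 and TXNIP, an inhibitor of glucose uptake, by -1.33. The list missed the threshold with the strict filter (adjusted p = 0.0808). A 7-gene set published for liver cancer cells under chronic hypoxia, not chosen on these samples, had 4 of 6 genes higher and 1 lower (camera adjusted p = 0.0379, adjusted p = 0.388 with an estimated correlation). CCNG2 changed by 1.58, with other probes at 1.37 and 0.12, and RCL1 by -0.37. Camera asks whether the members move 1 way, and the direction published for each member was not used in either line. A member published as falling would therefore count against the set. With only rows that have a symbol the adjusted p was 0.0643. Several lists did not pass camera in Caco2. In the tricarboxylic acid cycle 1 rose and 6 fell of 21 (adjusted p = 0.287), and 0 rose and 6 fell adjusted over the list alone. Among HIF pathway regulators 5 rose and 3 fell of 11 (0.204), and 5 rose and 4 fell adjusted over the list alone. With the dye term and pair block that list passed (adjusted p = 0.00726). The others were cholesterol synthesis (8 rose and 4 fell of 25, 0.189), fatty acid metabolism (8 rose and 8 fell of 24, 0.917), and interferon response (7 rose and 1 fell of 20, 0.15). So were pancreatic duct and acinar genes (6 rose and 2 fell of 12, 0.0962) and drug metabolism (7 rose and 7 fell of 21, 0.69). The pancreatic list passed with the dye term and pair block (adjusted p = 0.00664), the strict filter (0.0207) and median centring (0.0412). It also passed without Caco2 replicate 2 (0.0331) and with Caco2 replicate 1 from array 1 alone (0.0479). Markers of other cell types did not pass either: fibroblast (2 rose and 0 fell of 6, 0.396), endothelial (3 rose and 0 fell of 4, 0.111) and leukocyte genes (3 rose and 2 fell of 7, 0.398). By fry, 8 of these lists passed in Caco2 (adjusted p from 0.00785 to 0.0433). The tricarboxylic acid cycle passed as lower. Cholesterol, fatty acid, pancreatic, HIF regulator, fibroblast, endothelial and leukocyte genes passed as higher. The macrophage receptor gene CSF1R rose by 2.71 ± 0.11. In every Caco2 list without a second count, the counts adjusted over the list alone were equal.

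Among genes with a symbol and the same direction on all 4 arrays, the largest Caco2 increases besides ADM were those of PREX1, an activator of Rac (3.63 ± 0.087; chromosome 20, 46675026 to 46675084), the alkaline phosphatase gene ALPG (3.59 ± 0.086; chromosome 2, 232983591 to 232983650) and TMCC1 (3.50 ± 0.096). Next came the lymphotoxin gene LTB (3.35 ± 0.10), the long noncoding RNA UCA1 (3.30 ± 0.11), the water channel gene AQP10 (3.26 ± 0.078) and RGS2, a regulator of G proteins (3.25 ± 0.12). Other probes gave smaller increases for ALPG (1.83), TMCC1 (1.28 and 0.81) and AQP10 (0.95). The largest decreases were those of MAT2A, the enzyme that makes S-adenosylmethionine (-2.51 ± 0.084; chromosome 2, 85625813 to 85625872), the apolipoprotein gene APOH (-2.25 ± 0.10; chromosome 17, 61638667 to 61638726) and the mitochondrial-encoded CYTB (-2.08 ± 0.21), chosen in the same way. They were followed by BFSP1 (-2.01 ± 0.099), SPTSSB (-1.95), PAGE4 (-1.79), IGDCC3 (-1.78) and PRDM13 (-1.77). In all, 8563 of 18416 genes (46.5%) changed in Caco2, 4229 upward and 4334 downward. Of these, 770 rose and 326 fell by at least 2-fold. The count fell to 3336 without Caco2 replicate 1 and to 2922 without Caco2 replicate 2. The spread then came from HPAC, and the remaining pair was assumed to vary alike.

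The comparison within HPAC asks the same question of pancreatic cancer cells. By camera with a preset correlation, HIF targets, glycolysis genes, collagen-modifying genes and metallothioneins were higher as lists at 2% O2. The lists of stress response (15 of 25 genes lower), DNA replication (15 of 30), cholesterol synthesis (12 of 25) and respiratory chain genes (19 of 40) were lower. With an estimated correlation, which passed no list at all, these calls were lost (adjusted p from 0.369 to 0.423). By fry each passed in the same direction (adjusted p from 0.0029 to 0.0211). EGLN3 was 5.96-fold higher (log2 2.57 ± 0.084, adjusted p = 6.9e-05; chromosome 14, 33464392 to 33464451) and CA9 5.43-fold higher (2.44 ± 0.092). ADM rose by 1.88 ± 0.10, PDK1 by 1.44 ± 0.088 and NDRG1 by 1.35 ± 0.078, each on all 4 arrays. LDHA rose by 0.62 ± 0.12 from 1 RNA pair, and with median centring its change was 0.36 (adjusted p = 0.0876). EPAS1 (0.28 ± 0.094, adjusted p = 0.0542), VEGFA (0.14 ± 0.079, adjusted p = 0.215) and HIF1A (0.13 ± 0.12, adjusted p = 0.431) did not pass. Other VEGFA probes gave 0.13 to 0.54 in HPAC. EPAS1 in HPAC passed with the dye term and pair block (adjusted p = 0.0211) and without HPAC replicate 1 (0.38, adjusted p = 0.0135). So did HIF1A in HPAC without HPAC replicate 1 (0.36, adjusted p = 0.0163). BNIP3 was not measured in HPAC: each channel type was above background on 1 of 4 arrays.

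Of the HIF target genes measured in HPAC, 22 of 26 rose and 0 fell (camera adjusted p = 2.21e-12, adjusted p = 0.369 with an estimated correlation). PPP1R3C, a glycogen-targeting protein, changed by 2.16 and PPFIA4 by 2.10. Glycolysis and glucose uptake genes rose in 19 of 25 cases (camera adjusted p = 2.37e-08, adjusted p = 0.388 with an estimated correlation), with PFKFB4 at 2.30 and ENO2 at 2.07. Collagen-modifying genes rose in 10 of 14 cases and 1 fell (camera adjusted p = 0.000324, adjusted p = 0.422 with an estimated correlation). The crosslinking enzyme genes LOXL2 (1.95), LOX (1.91) and LOXL4 (1.25) rose. Of the metallothioneins 10 of 11 rose (camera adjusted p = 8.17e-06, adjusted p = 0.388 with an estimated correlation), led by MT1F at 1.83. Of 16 NF-kB genes 6 rose and 1 fell (camera adjusted p = 0.0125, adjusted p = 0.516 with an estimated correlation). The counts were 11 up and 2 down adjusted over the list alone. TNFAIP3 rose by 0.89 and ICAM1, an adhesion molecule, by 0.62. This call was lost without HPAC replicate 2 (adjusted p = 0.141) and by fry (adjusted p = 0.116). Of 11 HIF pathway regulators 3 rose and 0 fell (camera adjusted p = 0.0312, adjusted p = 0.388 with an estimated correlation). The counts were 6 up and 0 down adjusted over the list alone. The 3 that rose were EGLN3, CITED2 (1.43) and EGLN1, all of which are also on the HIF target list. That call was lost with the deposited value table (adjusted p = 0.076), with the mean of a gene's probes (adjusted p = 0.101) and without HPAC replicate 2 (adjusted p = 0.0789).

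The stress list went down in HPAC: 15 of 25 members fell and 4 rose (camera adjusted p = 0.0019, adjusted p = 0.423 with an estimated correlation). The counts were 4 up and 16 down adjusted over the list alone. The members that fell include genes that make amino acids or respond to their shortage: the asparagine synthetase gene ASNS (-3.53 ± 0.12), PSAT1 (-3.10 ± 0.13), TRIB3 (-2.63 ± 0.098) and the mitochondrial folate enzyme gene MTHFD2 (-1.69 ± 0.11). ASNS and PSAT1 rest on 1 RNA pair and so were not in the camera test, while ATF3 rose by 0.73. Of the DNA replication and repair genes 15 of 30 fell and 1 rose (camera adjusted p = 0.002, adjusted p = 0.388 with an estimated correlation). The helicase subunit genes MCM6 (-1.49), MCM3 (-1.24) and MCM2 (-1.16) fell. Cholesterol synthesis and uptake genes fell in 12 of 25 cases and 0 rose (camera adjusted p = 0.002, adjusted p = 0.388 with an estimated correlation). The counts were 0 up and 13 down adjusted over the list alone. DHCR7, a late step of the pathway, changed by -0.59. Of the respiratory chain genes 19 of 40 fell and 0 rose (camera adjusted p = 0.000138, adjusted p = 0.388 with an estimated correlation). The counts were 0 up and 21 down adjusted over the list alone. CYCS, which encodes cytochrome c, changed by -1.25, with other probes at -0.079 and -0.48, and CYC1 changed by -0.56. Wnt targets and stem cell genes fell in 7 of 14 cases and 1 rose (camera adjusted p = 0.0472, adjusted p = 0.516 with an estimated correlation). AXIN2 changed by -1.28 (-0.87 with another probe) and the cyclin gene CCND1 by -1.02. That list missed the threshold without HPAC replicate 2 (adjusted p = 0.114) and with the strict filter (adjusted p = 0.0609). It also missed it with the mean of a gene's probes (adjusted p = 0.0618) and with only rows that have a symbol (adjusted p = 0.072).

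Mitosis genes in HPAC did not move as a list: 6 rose and 4 fell of 31, with a median of 0.05 (camera adjusted p = 0.19). The median was -0.18 with median centring and -0.13 without HPAC replicate 1. Without HPAC replicate 2 the list passed as higher (adjusted p = 0.0489). NUSAP1, a spindle protein, rose by 0.72, and CCNE1, a cyclin of the G1 to S transition, changed by -0.67. Other lists did not pass in HPAC either. In fatty acid metabolism 4 rose and 7 fell of 24 (adjusted p = 0.126), and 4 rose and 9 fell adjusted over the list alone. In drug metabolism 4 rose and 5 fell of 13 (0.439), and 4 rose and 6 fell adjusted over the list alone. The rest were the tricarboxylic acid cycle (3 rose and 8 fell of 20, 0.111), interferon response (6 rose and 2 fell of 22, 0.287) and epithelial junctions and mesenchymal transition (7 rose and 7 fell of 17, 0.69). They also include pancreatic duct and acinar genes (2 rose and 3 fell of 12, 0.676), demethylases (5 rose and 0 fell of 14, 0.0913), the 7-gene set (3 rose and 1 fell of 6, 0.147) and enterocyte genes (1 rose and 0 fell of only 4 measured, 0.795). Without a filter on dim probes the tricarboxylic acid cycle passed (adjusted p = 0.0379). The demethylases passed without that filter (adjusted p = 0.0268), with the dye term and pair block (0.0474) and without HPAC replicate 1 (0.0453). The 7-gene set passed with the dye term and pair block (adjusted p = 0.000911) and with median centring (0.0344). By fry, the tricarboxylic acid cycle, fatty acid and pancreatic lists passed as lower in HPAC, and the demethylases and the 7-gene set as higher (adjusted p from 0.00785 to 0.0339). Iron and heme genes (6 rose and 5 fell of 15, 0.954) had a mean of 0.17, a median of -0.12 and a downward test. The copper-carrying ferroxidase gene CP rose by 2.63 ± 0.23 and the transferrin receptor gene TFRC changed by -1.30. Glucocorticoid-responsive genes (3 rose and 1 fell of 9, 0.953) had a downward test with a median of 0.094 and a mean of 0.21. Fibroblast markers did not pass (1 rose and 0 fell of 4, 0.676). Of 4 leukocyte markers 1 rose and 1 fell (0.953), and 1 rose and 2 fell adjusted over the list alone, with a median of -0.071, a mean of 0.16 and an upward test. With 2 measured members, 1 of which fell, endothelial markers were not tested. In every HPAC list without a second count, the counts adjusted over the list alone were equal.

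The largest HPAC increases besides EGLN3, CA9 and PFKFB4, among genes with a symbol and the same direction on all 4 arrays, were those of the acid phosphatase gene ACP5 (2.72 ± 0.092; chromosome 19, 11546525 to 11546584), CP and the endothelin gene EDN2 (2.62 ± 0.13; chromosome 1, 41717043 to 41717102). Then came the ribonuclease gene RNASE4 (2.28 ± 0.093) and the annexin gene ANXA8 (2.24 ± 0.081). By the same rule, the largest decreases were those of CTH, which makes cysteine (-3.37 ± 0.18; chromosome 1, 70677629 to 70677688), TRIB3 (chromosome 20, 326107 to 326166) and the methionyl-tRNA synthetase gene MARS1 (-2.19 ± 0.14). They were followed by the ribosome assembly gene RRS1 (-2.13 ± 0.082), GRB10 (-2.11 ± 0.14, and -1.45 with another probe) and the amino acid transporter gene SLC7A5 (-2.06 ± 0.15, and -0.92 with another probe). The list ends with the CTP synthase gene CTPS1 (-2.04 ± 0.080) and the transaminase gene GPT2 (-1.98 ± 0.094). In all, 7216 of 17935 genes (40.2%) changed, 3643 upward and 3573 downward. Of these, 343 rose and 315 fell by at least 2-fold. Fitted alone, or with either Caco2 replicate left out, HPAC gave 4808 genes, since its own pairs differ more from each other. All changes are relative to the centre that loess sets, and with median centring the median of all genes moved to -0.13 in HPAC and -0.088 in Caco2.

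The difference between the lines asks which hypoxia changes depend on the cell line, and the largest gap between lists was in the stress genes. Of 25 stress list members, 19 had a lower change in HPAC than in Caco2 and 0 a higher one, with a median HPAC minus Caco2 difference of -1.64 (camera adjusted p = 2.01e-10, adjusted p = 0.442 with an estimated correlation). TRIB3 differed by -4.35 ± 0.14 and CTH, which is not on that list, by -4.63 ± 0.26 (adjusted p = 0.000197); both rose in Caco2 and fell in HPAC. ASNS changed by -0.083 in Caco2, where another probe gave 0.56. Mitosis genes went the other way, with a higher change in HPAC than in Caco2 for 21 of 31 and a lower one for 2 (median difference 0.70; camera adjusted p = 1.15e-05, adjusted p = 0.442 with an estimated correlation). The change of the HIF list was lower in HPAC than in Caco2 (median HPAC minus Caco2 difference -0.48; camera adjusted p = 0.000307, adjusted p = 0.442 with an estimated correlation). So was that of the glycolysis genes (median difference -0.59; camera adjusted p = 1.95e-05, adjusted p = 0.499 with an estimated correlation). Of the genes fixed in advance, CA9 (-0.53), ADM (-1.48), PDK1 (-0.92), NDRG1 (-0.68), LDHA (-0.87) and VEGFA (-1.42) responded less in HPAC. For VEGFA this is the smallest difference among its 4 probes. HIF1A differed by 0.81. EGLN3 (0.22 ± 0.12, adjusted p = 0.191) and EPAS1 (-0.32 ± 0.13, adjusted p = 0.103) did not pass the test of the difference.

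**Figure D2:**
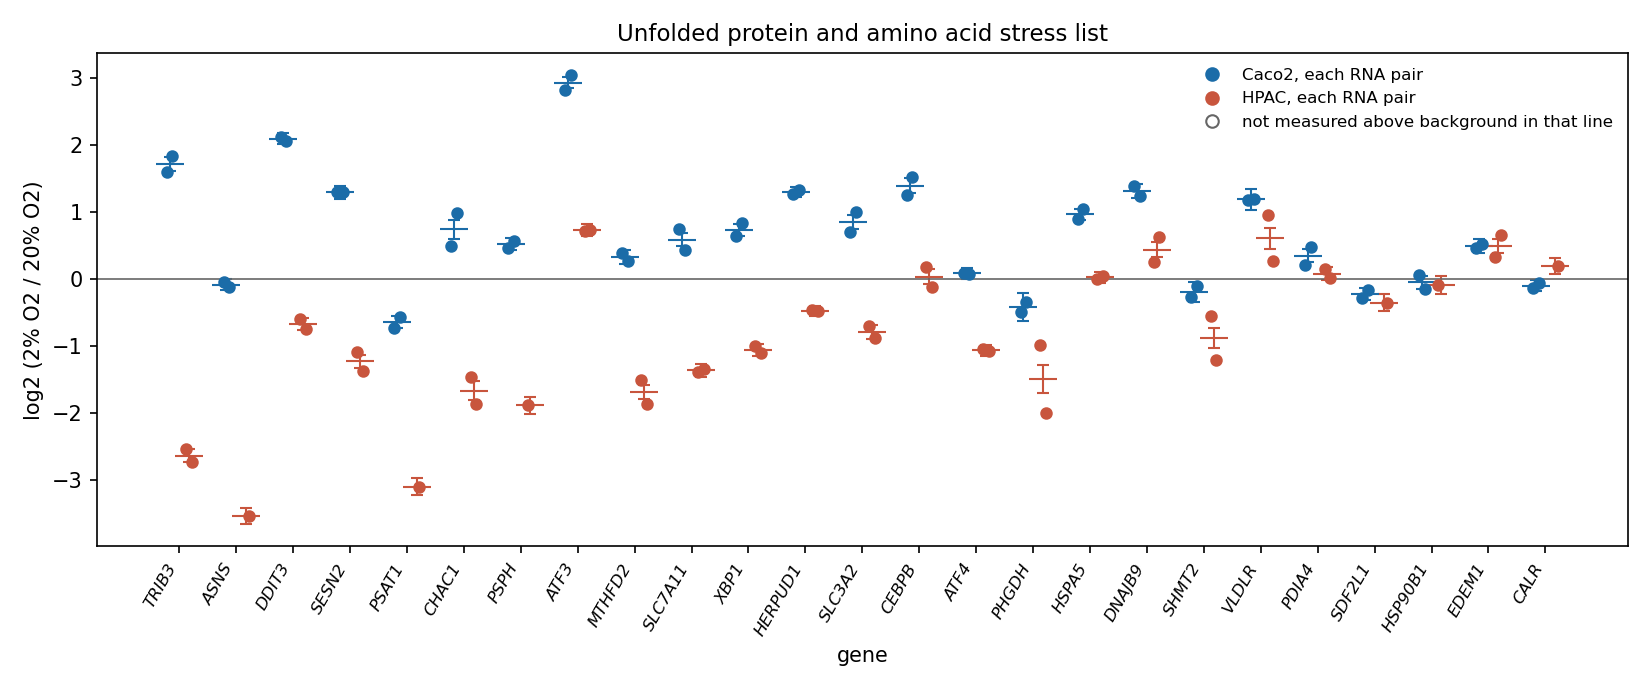
Log2 ratio of 2% over 20% O2 (y axis) for each gene of the unfolded protein and amino acid stress list (x axis), with blue for Caco2 and red for HPAC; dots are single RNA pairs, horizontal bars the mean and error bars the SE. TRIB3 lies at 1.72 in Caco2 and -2.63 in HPAC, and ASNS at -0.083 and -3.53, where HPAC has 1 dot because its other RNA pair is missing.

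**Figure D3:**
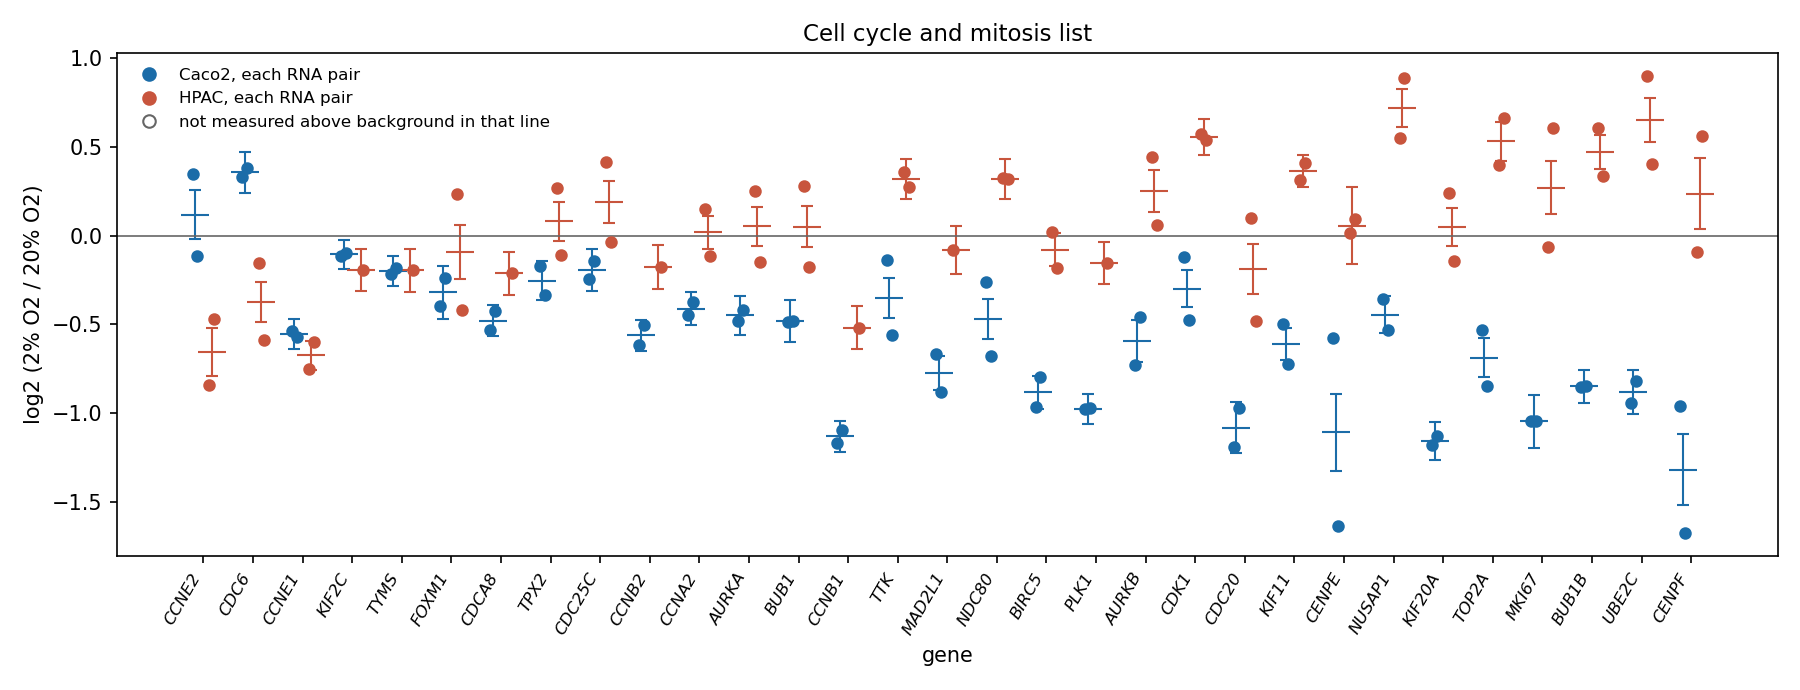
Log2 ratio of 2% over 20% O2 (y axis) for each gene of the cell cycle and mitosis list (x axis), with blue for Caco2 and red for HPAC; dots are single RNA pairs, horizontal bars the mean and error bars the SE. KIF20A lies at -1.15 in Caco2 and 0.046 in HPAC, and UBE2C at -0.88 and 0.65.

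Further lists differed, all with a lower median change in HPAC. Metallothioneins differed by a median of -1.33 (camera adjusted p = 0.00495, adjusted p = 0.527 with an estimated correlation) and NF-kB genes by -0.92 (camera adjusted p = 8.08e-05, adjusted p = 0.511 with an estimated correlation). Epithelial junction and mesenchymal genes differed by -0.50 (camera adjusted p = 0.0075, adjusted p = 0.442 with an estimated correlation). For cholesterol genes the median was -0.45 (camera adjusted p = 0.00726, adjusted p = 0.442 with an estimated correlation) and for pancreatic duct genes -0.75 (camera adjusted p = 0.00726, adjusted p = 0.442 with an estimated correlation). The 4 enterocyte genes measured in both lines differed by -0.88 (camera adjusted p = 0.0283, adjusted p = 0.442 with an estimated correlation). That call was lost with median centring (adjusted p = 0.0829) and the strict filter (0.103), and the pancreatic one without a filter (0.0551). S100P, a marker of pancreatic tumours, rose by 1.39 in Caco2 and changed by -1.01 in HPAC, and OCLN changed by 0.73 and -1.14. The difference in the other tested lists did not pass, with adjusted p from 0.213 for demethylases to 0.774 for the respiratory chain. Without a filter the glucocorticoid list passed (adjusted p = 0.0199). By fry that list, the fatty acid list, the iron list and the 7-gene set passed (adjusted p from 0.0162 to 0.0298). For collagen-modifying and DNA replication genes, median and mean differ in sign. Single differences were ranked among genes with a symbol, both RNA pairs in each line, and both pairs of one line above both of the other. The largest above Caco2 were those of ANKRD36B (3.43 ± 0.24), RNASE4 (2.99 ± 0.13), and BFSP1 (2.27 ± 0.14). Next were the antimicrobial peptide gene DEFB1 (2.22 ± 0.17), the lipoxygenase gene ALOX15B (2.15 ± 0.11) and the ribonuclease gene ANG (2.09 ± 0.11), which shares promoters with RNASE4. ANKRD36B belongs to a family of close copies, and its other probes gave 0.60 and 0.45 in HPAC, against 1.73 for the one used. In Caco2 they gave -0.073, not measured above background there, and -0.25, against -1.70. The large difference thus rests on 1 probe. By this rule the largest below Caco2 after CTH and TRIB3 were PLAC8 (-4.16 ± 0.11), the keratin gene KRT80 (-3.85 ± 0.13), TMCC1 (-3.46 ± 0.14) and NRN1 (-3.30 ± 0.11). Another NRN1 probe changed by 2.01 in Caco2, against 3.22 for the one used. In all, 6045 of 16474 genes (36.7%) differed, 2888 upward and 3157 downward in HPAC relative to Caco2. Of these, 570 and 815 differed by at least 2-fold. The count was 2484 without Caco2 replicate 1 and 1804 without Caco2 replicate 2, and the lines were on separate slides.

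**Figure D4:**
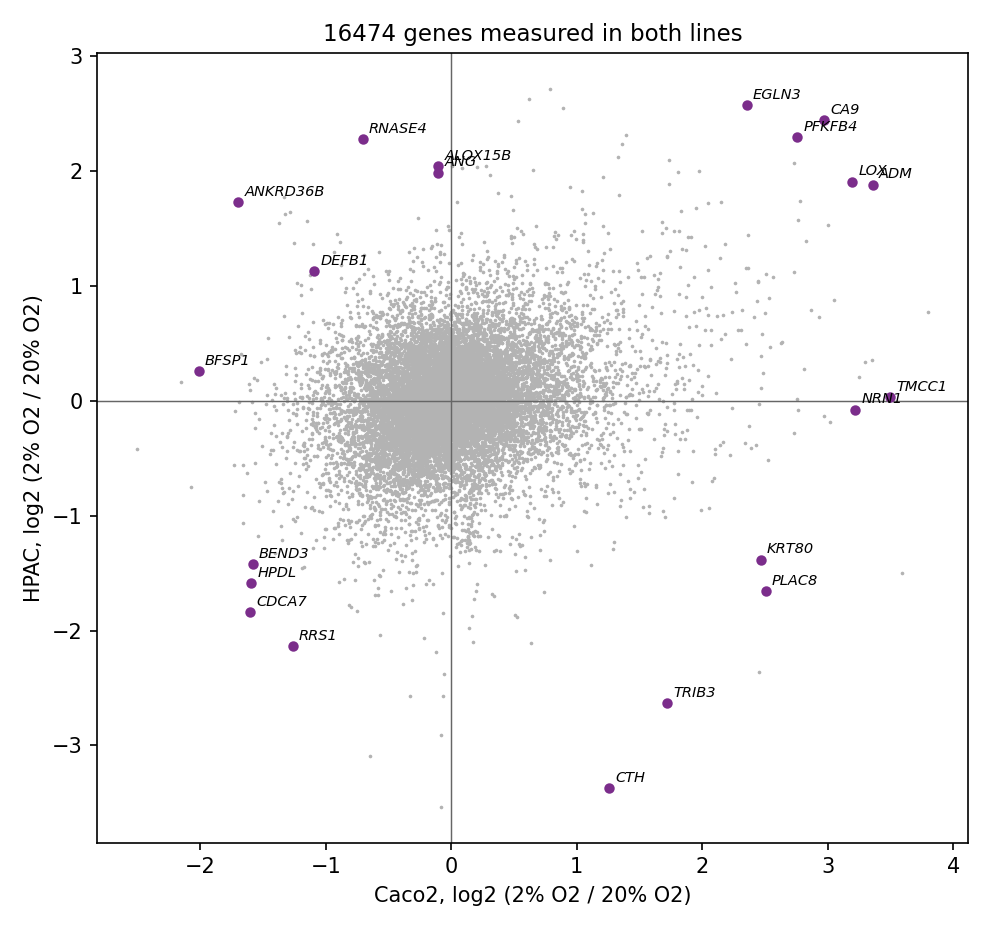
Log2 ratio of 2% over 20% O2 in Caco2 (x axis) against that in HPAC (y axis) for the 16474 genes measured in both lines, each dot a gene with its mean of the RNA pairs; purple dots are genes named for the difference or the average. CA9, EGLN3 and PFKFB4 lie above 2 in both lines, and TRIB3 lies at 1.72 in Caco2 and -2.63 in HPAC.

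The average over both lines asks for a shared response. Among genes with a symbol and the same direction on all 8 arrays, its largest increases were those of CA9 (2.71 ± 0.065, adjusted p = 9.77e-06), ADM (2.62 ± 0.072), LOX (2.55 ± 0.067; chromosome 5, 121433685 to 121433744), PFKFB4 (2.53 ± 0.10) and EGLN3 (2.46 ± 0.059). Its largest decreases were those of CDCA7, a MYC and E2F target gene (-1.72 ± 0.065; chromosome 2, 173941736 to 173941795), RRS1 (-1.70 ± 0.058), HPDL (-1.59 ± 0.070), BEND3 (-1.50 ± 0.078) and CYTB (-1.41 ± 0.15). On average 7965 of 16474 genes (48.3%) changed, 3914 upward and 4051 downward. Of these, 246 rose and 89 fell by at least 2-fold. The average can pass where a single line carries the change, so the overlap was counted as well. Increases in both lines numbered 1167, against 704 expected were the calls independent (odds ratio 2.53). Decreases in both numbered 1314, against 779 (odds ratio 2.72). Of the 3586 genes called in both lines, 1105 were called in opposite directions, which is fewer than independent calls would give. Across 15901 genes, which are not independent replicates, the changes of the lines had a Pearson correlation of 0.235 and a Spearman correlation of 0.209. The RNA pairs of a line were closer, at 0.941 in Caco2 and 0.790 in HPAC, and pairs of different lines ranged from 0.10 to 0.30. Without Caco2 replicate 1 the average passed for 4202 genes, and without Caco2 replicate 2 for 4179.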

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

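The tests of the dye orientation and of a single deviating RNA pair were chosen after the result was seen; the other tests and the gene lists they use were set before their result was seen, though after the comparisons above. The lines differed most in the stress list, by a median of -1.64 in HPAC relative to Caco2 in the test of the difference. A dye effect that changes sign when the dyes are swapped cancels in the mean of an RNA pair, so the dye orientations do not test it as a cause. The median difference was -1.58 in the arrays with hypoxia in red and -1.42 in those with hypoxia in green, so it did not come from 1 orientation alone. Over 5 other background corrections and normalizations the median difference stayed at -1.61 or beyond. A single deviating RNA pair does not account for it, since the smallest median among the 4 combinations of single pairs was -1.40. Slide and line cannot be told apart, since each line was on a slide of its own. What also stays open, as a hypothesis found and tested on the same data, is that an amino acid response driven by the transcription factor ATF4 may be lower in hypoxic HPAC cells. The 10 tRNA synthetases known as ATF4 targets, none on the list, had a median of -1.23 in HPAC against -0.30 for 8 others, a gap of -0.92 (exact permutation test over genes, two-sided p = 0.0008, with genes treated as independent), while in Caco2 the medians were 0.24 and -0.069; a cause such as nutrient supply in the flasks was not tested.

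For the mitosis list the lines differed by a median of 0.70. Over the 5 other processings the smallest value was 0.70, and over the combinations of single RNA pairs 0.55 (0.546). With hypoxia in red it was 0.68 (0.682) and with hypoxia in green 0.86. These values argue against the normalization and 1 deviating pair, while slide and line cannot be told apart here either. The difference was present in both dye orientations, but a dye effect that changes sign cancels in the pair means and was not tested by them. A shift between cell cycle phases in opposite directions may be involved: over genes outside the fixed lists, the median change of G2 and mitosis genes minus that of G1 and S genes was -0.50 in Caco2 and 0.42 in HPAC, a gap of -0.92 (-0.9214). In HPAC the G2 and mitosis genes did not pass by themselves (median 0.12, camera adjusted p = 0.185), and the G1 and S genes were lower (median -0.30, camera adjusted p = 0.0113). This is a hypothesis found and tested on the same data, with genes of the same processes as the lists already seen, so the test is not independent. RNA levels do not count cells in a phase, and slower growth of a line at higher density was not tested.

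The test of the difference between the lines also called the HIF list (median -0.48), glycolysis (-0.59), cholesterol synthesis (-0.45), metallothioneins (-1.33), NF-kB (-0.92), epithelial junctions and mesenchymal transition (-0.50), enterocyte (-0.88) and pancreatic duct genes (-0.75). With an estimated correlation, where the spread rests on 2 residual degrees of freedom, none of the lists passed this test. The adjusted p was 0.442 to 0.527 for those named here, the stress list and the mitosis list. In the count over all genes 6045 differed. By the same test HPAC lay above Caco2 for ANKRD36B (3.43, with smaller changes by its other probes), RNASE4 (2.99), BFSP1 (2.27), DEFB1 (2.22), ALOX15B (2.15), ANG (2.09) and HIF1A (0.81). It lay below for CTH (-4.63), TRIB3 (-4.35), PLAC8 (-4.16), KRT80 (-3.85), TMCC1 (-3.46), NRN1 (-3.30), ADM (-1.48), VEGFA (-1.42), PDK1 (-0.92), LDHA (-0.87), NDRG1 (-0.68) and CA9 (-0.53). Of 203 genes named by the rule, 173 were measured in both lines, 130 passed the test of the difference and 30 were called in opposite directions. The rule picks genes partly by this test and by large changes or small p in a line. The share that passed is therefore raised by the choice and cannot be set against the 36.7% over all genes.

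Each of 6 measures of array quality was compared among the 4 arrays of each line. HPAC array 2 stood apart with 62.8% of probes above background in the hypoxia channel, and Caco2 array 2 with a correlation of 0.895 between the deposited value table and the log ratios of the same array. Chance marks about 1 in 20 such groups.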

How the results depend on the processing

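Taking Caco2 replicate 1 from array 1 alone, using only rows with a symbol and running the alternatives on the lists for the difference were chosen after seeing the data. No call on a list or a named gene changed direction in the settings where it was run. Values that did not pass could change sign, as the median of the mitosis list in HPAC did, and in all 4 comparisons the direction with more calls turned in some settings. For the difference it did so with Agilent's log ratios (2682 up, 2440 down) and the deposited value table (2751 and 2482). The correlation between the lines ranged from 0.157 to 0.291 over the 16 settings in which it was computed. Requiring 2-fold as well as the adjusted p left 1096 genes in Caco2, 658 in HPAC, 1385 for the difference and 335 for the average, by construction. Each line fitted alone gave 4808 genes in HPAC, with the spread between its own pairs, and 11278 in Caco2; the difference and the average cannot be had that way. Leaving out each RNA pair in turn gave 2922 to 11278 genes in Caco2, 4808 to 8466 in HPAC, 1804 to 8020 for the difference and 4179 to 9266 for the average, with fewer pairs and with the lone pair assumed to vary like those of the other line. All other settings kept these counts within 1.5 times, among them RNA extracts compared without their array pairing (7258, 5722, 4687 and 6817 genes), Agilent's log ratios (8079, 6177, 5122 and 7088), array 1 alone (7875, 6491, 5271 and 7354) and rows with a symbol (6384, 5209, 4436 and 5975). The split by direction depends on the centring: with median centring 35.5% of the Caco2 calls, 28.8% of the HPAC calls and 25.6% of those for the average were increases, against 49.4%, 50.5% and 49.1%, and the cause was not tested.

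Of 51 lists tested within the lines, 10 kept their side of the threshold in every setting where they were tested, and 48 were tested in all 20. An estimated correlation ended the call of 27 lists, and fry added 13 and ended 1. The dye term and pair block added 4, median centring and no filter 2 each. The strict filter, array 1 alone and leaving out Caco2 replicate 2, HPAC replicate 1 or HPAC replicate 2 added 1 each. With the strict filter, with only rows that have a symbol and without HPAC replicate 2, 3 ended each. The mean of a gene's probes ended 2, and the deposited value table and leaving out Caco2 replicate 1 ended 1 each. Of 25 lists tested for the difference, 11 kept their side in every setting where they were tested. An estimated correlation ended 10 of these calls and fry added 4, median centring and the strict filter ended 1 each, and no filter added 1 and ended 1. Of 263 results on named genes, 226 kept their side of the threshold in every setting that gave them a value, with 193 having one in all 18, and leaving out Caco2 replicate 1 or 2 ended 20 and 18. Signal over background limits what was tested: without a filter 31157 genes were tested and with the strict filter 15066.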

Other observations

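Lists chosen after seeing the comparisons above, and before their own test, describe further gene groups. Unless stated, their counts are adjusted over all genes, and counts adjusted over the list alone can differ. Transcripts encoded by the mitochondrial genome fell in 6 of 6 measured cases in Caco2, among them ND2 (-1.12) and ND3 (-1.23), with a median of -1.06 (camera adjusted p = 0.00178, adjusted p = 0.317 with an estimated correlation). CYTB, 1 of these 6, was already named above among the largest decreases, so it is not a new observation. In HPAC 1 rose and 2 fell of 6 (adjusted p = 0.289), and the difference between the lines passed (camera adjusted p = 0.00409, adjusted p = 0.473 with an estimated correlation). Mitochondrial ribosome genes fell in 12 of 24 cases in Caco2 (camera adjusted p = 0.0113, adjusted p = 0.3 with an estimated correlation) and in 13 of 24 in HPAC (camera adjusted p = 0.000167, adjusted p = 0.282 with an estimated correlation). Immediate early genes, which answer to signals within minutes, rose in 15 of 19 cases in Caco2 (camera adjusted p = 2.19e-06, adjusted p = 0.282 with an estimated correlation), with the zinc finger genes ZFP36 at 2.47 and KLF4 at 2.34. In HPAC 6 rose and 1 fell of 18 (adjusted p = 0.366), and the difference passed (camera adjusted p = 1.72e-05, adjusted p = 0.323 with an estimated correlation).

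In Caco2 6 of 13 genes of MHC class I and antigen processing rose (camera adjusted p = 0.0407, adjusted p = 0.3 with an estimated correlation), against 3 of 12 in HPAC (adjusted p = 0.201). Of the autophagy genes 7 of 15 rose (camera adjusted p = 0.0306, adjusted p = 0.3 with an estimated correlation), against 5 of 15 with 2 lower in HPAC (adjusted p = 0.219). Neither difference between the lines passed (adjusted p = 0.501 and 0.478). GABARAPL1, which takes part in forming autophagosomes, rose by 1.14 in Caco2 and 0.97 in HPAC. Proteasome genes fell in 8 of 23 cases in HPAC (camera adjusted p = 0.000584, adjusted p = 0.282 with an estimated correlation), and in Caco2 1 rose and 6 fell of 24 (adjusted p = 0.126). Adjusted over the list alone, 0 rose and 3 fell in Caco2. In HPAC all 10 tRNA synthetases known as ATF4 targets fell (camera adjusted p = 6.31e-07, adjusted p = 0.317 with an estimated correlation), such as GARS1 (-1.70), and of the others 1 rose and 4 fell of 8 (adjusted p = 0.126). In Caco2 the counts were 4 rose and 0 fell of 10 (adjusted p = 0.179) and 1 rose and 1 fell of 8 (adjusted p = 0.613). Of further G2 and mitosis genes 15 of 20 fell in Caco2 (camera adjusted p = 5.01e-05, adjusted p = 0.3 with an estimated correlation), and in HPAC 4 rose and 1 fell (adjusted p = 0.185). Of further G1 and S genes 10 of 22 fell in HPAC (camera adjusted p = 0.0113, adjusted p = 0.3 with an estimated correlation), and in Caco2 1 rose and 7 fell (adjusted p = 0.0992).

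Since RRS1 fell in both lines, a hypothesis was that hypoxia may lower transcripts of ribosome biogenesis in both. Of 25 other such genes chosen without looking at their values, 17 fell and 1 rose in Caco2 (camera adjusted p = 0.000105, adjusted p = 0.282 with an estimated correlation), and 23 fell and 0 rose in HPAC (camera adjusted p = 1.47e-12, adjusted p = 0.282 with an estimated correlation). The median was -0.47 (-0.4729) in Caco2 and -0.83 in HPAC, so the values that the hypothesis needs are there; whether ribosome production changed was not measured.

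Rows without a gene symbol moved differently from named genes. In Caco2 34.2% of their calls were increases, against 54.8% of those for named genes, and in HPAC 57.4% against 47.7%, gaps of 20.6 and -9.75 percentage points. Within 5 classes of brightness the mean gap was 19.5 points in Caco2 (SE over the classes 6.84), from 36.1 in the dimmest class to -1.15 in the brightest. In HPAC it was -4.19 points, between the values set for either outcome. Dim probes and another cause cannot be told apart in either line, since the Caco2 gap goes with brightness and its mean clears the set value by less than its SE. The background correction and normalization cannot be told apart from other causes either, as the gap moved without vanishing. In HPAC it was -6.60 points with Agilent's log ratios and -16.6 with median centring. In Caco2 it was 14.0 with median centring and 22.8 with Agilent's log ratios. No biological explanation was tested for these rows.

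The assignment of hypoxia within the 4 RNA pairs can be made in 8 ways, mirror images counted once, and 1 of the 8, the real one, gave as many as 7965 genes on average. The highest other gave 6045, and it is the assignment that turns the sign of one line, which equals the difference between the lines. The remaining 6 gave 0. The 8 ways are too few for a share under 0.05.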
